A study of Caenorhabditis elegans with 2 samples.

How the data were processed

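The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) of AMA-1, the large subunit of RNA polymerase II, in whole young adult Caenorhabditis elegans of both sexes. Per the labels, the worms were of strain YL489, which carries a transgene in which the pie-1 promoter drives AMA-1 fused to GFP and FLAG, followed by the puf-5 3′ untranslated region, together with an unc-119 rescue gene. The labels name AMA-1 as the antibody target and describe the line as expressing the tagged protein. Whether the antibody bound the tag or AMA-1 itself is not given in the sources used here, so the precipitated chromatin could come from germline cells alone or from every tissue. Chromatin was fragmented by sonication, per the labels. There were 2 samples, numbered in the labels as biological replicates 1 and 2 of a single group, and both were used. A control experiment named in the labels was not analysed here, and the data contain no second condition.

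The deposited files were peak lists. Per the names the submitters gave them, each replicate has a list of candidate peaks and background regions prepared as input for the irreproducible discovery rate (IDR) procedure, the pooled replicates have such a list, and a final list holds the optimal peaks past an IDR threshold, all for the genome builds ce10 and ce11. Peaks were thus called per replicate and on the pooled reads. The peak caller, its settings, the aligner, the IDR threshold and the way in which the control entered are not given in the sources used here. Each region has the authors' own signal value per the file format, deposited in column 7, whose scale is not given; it was used only to rank and describe regions within a list. The deposited column 9, the −log10 of a q-value per the file format, was at its highest value of 3.90 for all 887 optimal peaks and was not used to rank them. The lists hold no read counts, so the depth of each library is unknown and no interval for reads could be given. Intervals on shares below are exact Clopper-Pearson 95% intervals over peaks or genes and cover counting error only.

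The ce11 lists were the main data. Build ce11 is the assembly WBcel235, and no region ended beyond a reference chromosome. Genes came from the Ensembl release 115 annotation; protein-coding genes without a symbol there took the RefSeq symbol of the gene at the same place. A gene was called occupied when the summit of an optimal peak lay within 500 bp of its annotated 5′ end. Many worm genes are trans-spliced, so the annotated 5′ end of the transcript can lie downstream of the promoter.

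Shares of peaks were compared with 1000 circular shifts, in which all summits of a chromosome were moved by the same random distance. The overlap of replicates was the share of the 887 strongest regions of replicate 1 that shared at least 1 bp with one of the 887 strongest of replicate 2, tested one-sided; the other shift tests were two-sided. Shares of genes were compared by Fisher's exact test, two-sided, with the conditional odds ratio and its 95% interval, and Benjamini-Hochberg adjustment over the 11 annotated gene classes with at least 10 genes and, separately, over 22 gene lists. Signal ranks were compared by a permutation test with 100000 resamples. Genes and peaks along a chromosome are not independent replicates, so these p-values describe the lists and not the spread between animals. An adjusted p under 0.05 was taken as the threshold. The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated data, 200 of 887 peaks were placed at the 5′ ends of genes, within the 500 bp window. The gene step recovered 100% of those genes among 19985, which the placement fixes and which checks the code only. In 100 random sets of 887 independent nuclear peaks, 0.136% of the list tests and 6% of the shift tests, with 100 shifts each, passed the threshold. Peaks in the data need not be independent, so these rates may not hold for them.

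The tests, the gene lists and the rule for named genes were fixed before the data were examined. The lists were ribosomal proteins, translation factors, proteasome, constitutive chaperones, inducible heat shock genes, histones, spliceosome, RNA polymerase II and general transcription, 4 germline lists (proliferation and meiosis, P granule and small RNA pathway, oogenesis and maternal, chromatin), major sperm proteins, spermatogenesis, vitellogenins, intestine, muscle, neuron, neuropeptides, cuticle collagens, chemoreceptors and the 4 genes with sequence in the transgene. Members were matched by symbol, and names without a match in the annotation were left out. Named genes were the 4 transgene genes, the genes at the 10 strongest optimal peaks, and for each list up to 3 occupied members with the highest signal or, where fewer than 2 members were occupied, the first 2 unoccupied members. A peak was assigned to the protein-coding gene whose 5′ end was nearest within 500 bp, otherwise to the gene that contained the summit, otherwise to the nearest gene. Every occupied ribosomal protein gene was tabulated as well. The split of peaks into tRNA, snoRNA or snRNA, and protein-coding locations, the tests of tRNA genes by chromosome, and the additional named genes at nuclear peaks were chosen after the data had been seen. Alternatives were windows of 250 and 1000 bp, the 443 strongest optimal peaks, the 887 strongest regions of each replicate alone, other ways of assigning peaks to genes, autosomes only, background regions as the comparison set, other overlap rules and the ce10 lists; added later were tRNA results and all candidate regions in each replicate alone, peaks away from tRNA, snoRNA and snRNA genes, all pooled candidate regions, nuclear chromosomes only and lists without the transgene genes.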

Results

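AMA-1 occupancy was mapped by ChIP-seq in 2 biological replicates of young adult worms that carry a germline-driven, GFP- and FLAG-tagged copy of this RNA polymerase II subunit. The optimal list held 887 reproducible peaks, 858 on nuclear chromosomes and 29 on the mitochondrial genome, the latter being separate summits listed within only 2 called intervals. Nuclear peaks had a median width of 280 bp, and the list covered 235 kb, or 0.235% of the genome. The candidate lists behind it were far longer, with 28020 regions in replicate 1, 30000 in replicate 2 and 30000 in the pooled data. The 887 optimal peaks were the 887 strongest of the pooled regions. The division into tRNA, snoRNA and protein-coding sites, and the genes named at the strongest nuclear sites, were chosen after the data had been seen.

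The replicates shared their strongest regions far more often than shifted positions did, but only in part. Of the 887 strongest regions of replicate 1, 35.6% overlapped one of the 887 strongest of replicate 2, against a mean of 3.27% and a highest value of 4.06% in 1000 shifts (permutation p = 0.0010, the smallest that 1000 shifts can give). On nuclear chromosomes alone the overlap was 33.7% against 0.476%. Nearly all optimal peaks, 816 of 887 (92.0%), overlapped a candidate region in both replicates. Far fewer, 285 (32.1%), were among the 887 strongest of both, with 448 in replicate 1 and 571 in replicate 2. Across the 816 peaks found in both replicates, Spearman's rho between the 2 ranks was 0.135, and it was 0.0774 across the 798 nuclear ones. These correlations are across peaks, which are not independent replicates, and the peaks were selected on the pooled signal, which by itself can lower a correlation between the replicates.

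All 10 of the strongest peaks lay on the mitochondrial genome, whose genes are not templates of RNA polymerase II. Their summits were assigned to CYTB, ND5, ND2, ATP6, ND4 and COX1, which encode subunits of the respiratory chain and of ATP synthase. The strongest, in CYTB with its summit at position 4749, had a signal of 4717 and was first in both replicates. ND5 held the summits of ranks 2 and 3, which had these ranks in both replicates as well. The strongest nuclear peak had a signal of 237 and rank 24.

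The nuclear peaks were concentrated at small RNA genes. Summits within 250 bp of a tRNA gene made up 262 of the 887 peaks (29.5%, 95% interval 26.6 to 32.7%), against a mean of 0.325% in shifted sets, a ratio of 91.0. The share was 16.23% of the 887 strongest regions without replicate 2 and 30.9% without replicate 1. Another 68 peaks (7.67%) lay at snoRNA or snRNA genes, 26.8 times the shifted mean of 0.287%. Away from those genes, 209 peaks (23.6%) lay within 500 bp of a protein-coding 5′ end, 1.34 times the shifted mean, and 169 (19.1%) lay at a protein-coding 3′ end, 1.67 times the shifted mean. Summits in the bodies of protein-coding genes were scarcer than in shifted sets, at 10.03% against 42.7%, and so were summits elsewhere, at 6.88% against 24.5%. The shares at protein-coding ends, in gene bodies and elsewhere are all lowered by the order of assignment, since a summit at a small RNA gene is not counted there. Among only the nuclear peaks away from small RNA genes, 39.6% lay at a 5′ end against 18.6% in shifted sets (ratio 2.13). At 3′ ends the values were 32.0% against 11.96% (ratio 2.68). Each of these nuclear differences had the smallest p that the two-sided shift permutation test can give, 0.0020.

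**Figure D1:**
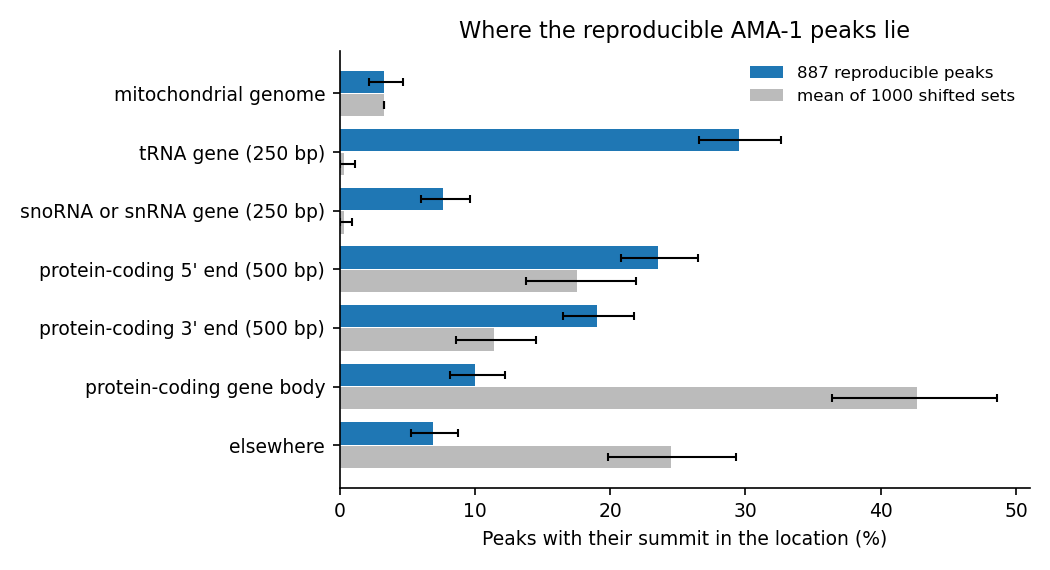
Share of the 887 reproducible peaks in each location in percent (blue, bars to the 95% Clopper-Pearson interval) and in 1000 shifted sets (grey, mean with bars to the lowest and highest set). Locations are exclusive and are assigned from top to bottom; tRNA genes held 29.5% of the peaks against 0.325% in shifted sets.

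Among gene classes, tRNA genes stood furthest apart. Of 612 nuclear tRNA genes, transcribed by RNA polymerase III, 303 (49.5%, 95% interval 45.5 to 53.5%) had a summit within 500 bp of their 5′ end, as did all 22 mitochondrial ones. With both included, the odds ratio against all other annotated genes was 63.6 (95% interval 53.4 to 75.8, Fisher's exact test). Summits sat on or close to the tRNA genes, a median of 13.5 bp upstream of the gene's middle (quartiles -41.4 and 26.5 bp), with 258 of 262 within 100 bp of it. Genes for tRNA-Cys (11 of 13) and tRNA-Glu (30 of 41, 73.2%) were occupied most often, whereas tRNA-Pro (13 of 42, 30.95%) and tRNA-Phe (3 of 14, 21.4%) were low among the amino acids; these differences between isotypes were not tested. Many tRNA genes share sequence, so a peak cannot always be assigned to a single copy. The odds ratio was 32.5 without replicate 2, 34.3 with a summit anywhere in the gene and 11.4 with all pooled candidate regions, all past the threshold. Occupancy was 56.7% for the 319 genes whose sequence occurs 10 or more times and 37.9% for the 140 whose sequence occurs once.

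Small nucleolar RNA genes, which encode guides for rRNA modification, were next, with 66 of 346 occupied (19.1%, odds ratio 10.6, 95% interval 7.93 to 14.03, adjusted p = 7.65e-40 by Fisher's exact test). They held the strongest nuclear sites. The nuclear peak of rank 24, on chromosome V from 8500452 to 8500684, lay at the snoRNA gene ZK994.7 in an intron of pxn-1, and ranked 24 in replicate 1 and 25 in replicate 2. Rank 25 fell at sls-2.4, an SL2 spliced leader RNA gene on chromosome I, with its summit at 4172345 and signal 202. In 10 of 11 alternatives the snoRNA class kept its call, with odds ratios of 5.77 to 16.3; with peaks away from small RNA genes, which removes most such sites, the odds ratio was 1.98 and did not pass. Further strong snoRNA sites were T19B4.8 (signal 175) on chromosome I and T03F7.8 (signal 158) in an intron of cutl-18 on chromosome V. The strongest nuclear tRNA site was F38G1.t2, in an intron of egl-17 on the X chromosome, with a signal of 146. The snRNA class had 9 of 129 genes occupied (odds ratio 3.21, 1.43 to 6.32, adjusted p = 0.00478 by Fisher's exact test). Its call was lost when each peak counted only for the nearest 5′ end (odds ratio 2.47) and with a summit anywhere in the gene (2.001), and the odds ratio was 5.88 without replicate 2.

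Protein-coding genes, whose nuclear members are transcribed by RNA polymerase II, were occupied much less often than tRNA and snoRNA genes. Of 19985 protein-coding genes, 314 (1.57%) were occupied, or 302 of 19973 without the 12 mitochondrial ones, fewer than among all other genes (odds ratio 0.547, 0.477 to 0.625, adjusted p = 6.83e-20 by Fisher's exact test; 0.543 on nuclear chromosomes). With peaks away from tRNA, snoRNA and snRNA genes, 242 protein-coding genes were occupied and the odds ratio was 3.13. That alternative drops the peaks of the small RNA genes but keeps these genes in the comparison. The occupied other genes thereby fell from 764 to 105, so this turn in direction was largely built in. The direction also turned when a summit anywhere in the gene was counted (odds ratio 1.57), or when all pooled candidate regions were used (odds ratio 1.53). Counting the whole gene gives longer genes more room for a summit, so that turn was in part built in as well. Occupied protein-coding genes rose from 314 to 907, while tRNA genes stayed at 325 and piRNA genes at 36. The annotated class of other noncoding RNA genes had 307 of 7764 occupied (odds ratio 2.05, adjusted p = 1.09e-22 by Fisher's exact test), of which 75 remained with peaks away from small RNA genes (odds ratio 1.39). When each peak counted only for the nearest 5′ end, 102 were occupied and the difference was lost (odds ratio 1.03). Genes for piRNAs, the small RNAs bound by PRG-1 in the germline, were rarely occupied, at 36 of 15363 (odds ratio 0.0688, exact adjusted p = 1.70e-131), and so were pseudogenes, at 6 of 2128 (odds ratio 0.115, exact adjusted p = 1.08e-14). Both stayed below the other genes and past the threshold in 11 alternatives, with odds ratios of 0.0237 to 0.3995 for piRNA genes and 0.05096 to 0.377 for pseudogenes. Genes for miRNAs did not pass (10 of 261, odds ratio 1.70, adjusted p = 0.119 by Fisher's exact test), but they did with a window of 1000 bp (odds ratio 1.95), with peaks away from small RNA genes (5.48) and with all pooled candidate regions (1.93). With peaks away from small RNA genes the same 10 miRNA genes were occupied, and only the occupied genes in the comparison fell, from 1068 to 337. No difference past the threshold was found for rRNA genes (2 of 22, both mitochondrial, exact adjusted p = 0.119), lincRNA genes (2 of 194, exact adjusted p = 0.369) or antisense RNA genes (1 of 100, exact adjusted p = 0.732).

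**Figure D2:**
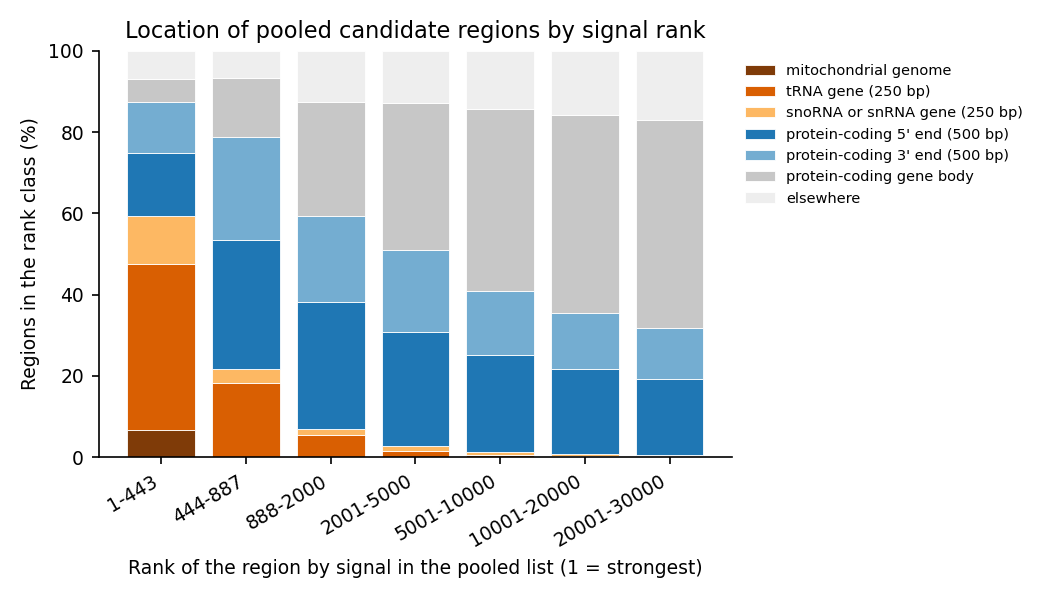
Location of the pooled candidate regions (percent of regions, y axis) by their rank in signal (x axis, strongest at left). The share at tRNA genes was 40.9% for ranks 1 to 443, 18.2% for ranks 444 to 887 and 0.16% for ranks 20001 to 30000, and the share in protein-coding gene bodies was 5.64% in the first class and 51.2% in the last.

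Both ends of protein-coding genes were occupied more often than shifted positions. Counting every peak whatever else was nearby, 285 summits (32.1%, 29.1 to 35.3%) lay within 500 bp of a protein-coding 5′ end, against a shifted mean of 19.96% (ratio 1.61). A further 229 (25.8%, 23.0 to 28.8%) lay within 500 bp of a 3′ end and near no 5′ end, against 12.04% (ratio 2.14). Both had the smallest two-sided permutation p, 0.0020. The strongest of the 209 peaks at 5′ ends away from small RNA genes was upstream of rpl-3, a protein of the large ribosomal subunit, on chromosome III from 3867508 to 3867650. Its signal was 106 and its rank 68. Next were the shared upstream region of rpl-20 and Y17G9B.5 on chromosome IV (signal 90.03), cox-5A, a cytochrome c oxidase subunit gene on chromosome III (signal 87.9), and egl-30, which encodes a Gq alpha protein, on chromosome I (signal 85.8). Other strong promoter-proximal peaks were at cdc-48.1, an AAA ATPase gene (signal 71.95), and rpac-19, a subunit gene of RNA polymerases I and III (signal 69.9). For all 285 peaks at 5′ ends, no difference in rank from the other peaks was detected (median percentile 46.4 against 51.5, permutation test, p = 0.160; on nuclear chromosomes 45.1 against 52.1, p = 0.0543). In a test chosen after the data had been seen, the 209 peaks away from small RNA genes ranked lower than the other nuclear peaks, which include those at tRNA genes, at a median percentile of 33.8 against 55.2 (permutation p = 1.0e-05, the smallest that 100000 resamples can give). Peaks at tRNA genes ranked higher than the other nuclear peaks, at a median percentile of 68.5 against 42.0 (permutation p = 1.0e-05, also the smallest possible).

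The X chromosome differed from the autosomes as a group in opposite ways for tRNA and protein-coding genes, but not from every single autosome. It holds 276 of the 612 nuclear tRNA genes, and 156 of them (56.5%) were occupied against 147 of 336 on autosomes (43.8%; odds ratio 1.67, 1.197 to 2.33, p = 0.00200 by Fisher's exact test). Of the 180 peaks on X, 129 were at tRNA genes. Protein-coding genes on X were occupied less often, 25 of 2731 (0.915%) against 277 of 17242 (1.61%; odds ratio 0.566, 0.359 to 0.855, p = 0.00515 by Fisher's exact test). Counting only peaks at 5′ ends away from small RNA genes, 9 X-linked and 233 autosomal genes were occupied (odds ratio 0.241, 0.109 to 0.467, p = 3.84e-07 by Fisher's exact test). Chromosome V was lower still than X before that restriction, at 36 of 4994 protein-coding genes (0.721%) and 22 of 78 tRNA genes (28.2%), whereas chromosome III had the highest protein-coding share (72 of 2640, 2.73%). The X difference for protein-coding genes did not pass the threshold with a window of 1000 bp (odds ratio 0.808), the 443 strongest peaks (0.788) or without replicate 1 (0.678). With a window of 250 bp it was larger (0.243). No difference was detected between genes in the middle and the outer parts of the autosomes, each divided into 3 parts of equal length, 113 of 6570 against 164 of 10672 (odds ratio 1.12, 0.873 to 1.44, p = 0.350 by Fisher's exact test). With a window of 1000 bp that odds ratio was 1.24, and without replicate 2 it was 1.37, both past the threshold.

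**Figure D3:**
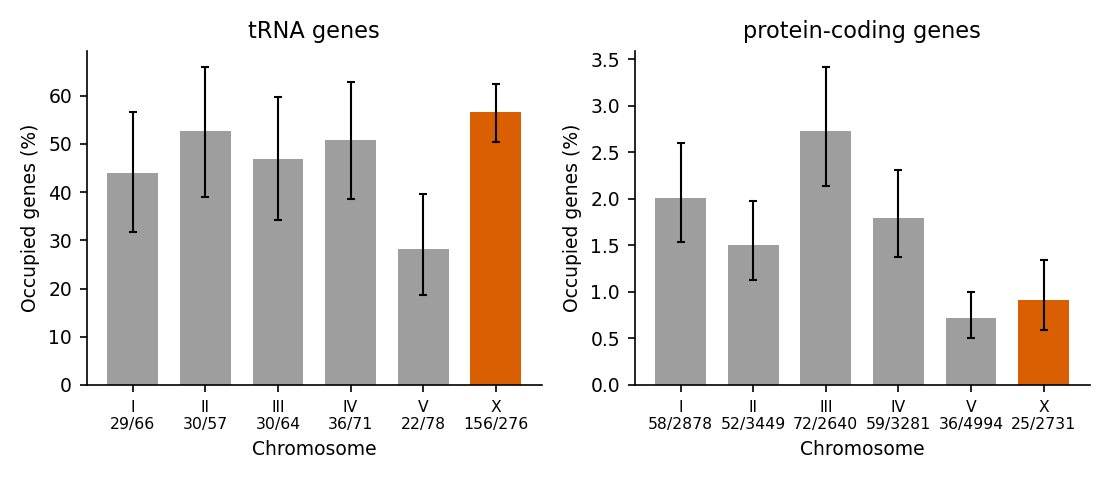
Percent of nuclear tRNA genes (left) and of protein-coding genes (right) occupied on each chromosome, with occupied and total genes under each bar, 95% Clopper-Pearson intervals as error bars and X in orange. On X 56.5% of tRNA genes and 0.915% of protein-coding genes were occupied; on V the shares were 28.2% and 0.721%.

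Genes in operon-like arrangements were occupied at their 5′ ends more often than others. In C. elegans, many genes that closely follow another on the same strand are transcribed with it as one unit. Of 3534 protein-coding genes whose same-strand neighbour ends at most 500 bp upstream, 101 (2.86%) were occupied, against 142 of 11278 (1.26%) whose upstream neighbour is on the other strand or over 2000 bp away. The odds ratio was 2.31 (1.76 to 3.01, p = 7.47e-10 by Fisher's exact test). For a downstream gene, the 500 bp window also takes in the 3′ end of the gene before it, and 3′ ends were enriched for peaks themselves. When a summit anywhere in the gene was counted, the odds ratio was 1.17 and did not pass the threshold.

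Ribosomal protein genes were the list with the highest call. Of 80, 16 (20%, 11.9 to 30.4%) were occupied against 1.497% of other protein-coding genes (odds ratio 16.44, 8.76 to 29.2, adjusted p = 2.26e-12 over the 22 lists by Fisher's exact test). Besides rpl-3 and rpl-20, they were rpl-15 (signal 72.3), rpl-35 (71.98), rps-19, rps-28, rps-20, rps-7, the divergent pair rpl-24.1 and rps-10, rps-25, rla-1, rpl-41.2, rps-16, rpl-6 and rpl-5. All 16 had a peak away from tRNA, snoRNA and snRNA genes. Most summits were upstream of the annotated start, for example by 296 bp at rpl-3, 367 bp at rpl-15 and 415 bp at rps-28. At 2 short genes the summit lay past the start, 475 bp at rla-1, in its 3′ untranslated region, and 467 bp at rpl-41.2, beyond the gene. With a window of 250 bp only 4 of 80 were occupied, and the list no longer passed (odds ratio 6.22). Without replicate 2 the odds ratio was 6.58, and with a summit anywhere in the gene it was 10.4, both past the threshold. Replicates ranked some of these sites very differently: rps-20 was at 23069 in replicate 1 and 360 in replicate 2, and rps-28 at 91 and 17568.

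Translation factors were the other list above the background, with 4 of 38 occupied (odds ratio 7.45, 1.91 to 21.1, exact adjusted p = 0.0212). These were eef-2 and eef-1A.2, which encode elongation factors, and eif-2gamma and eif-3.C, initiation factor genes; eif-3.C falls outside the rule for named genes and was added to complete the count. Their call was lost with either replicate alone (odds ratios 5.81 and 1.91) with either other window and with autosomes only. Chemoreceptor genes, which encode G protein-coupled receptors of sensory neurons, were rarely occupied, at 2 of 1308 (odds ratio 0.0901, 0.0109 to 0.329, exact adjusted p = 2.46e-06). The pair was srh-269, where the peak lay at a tRNA gene, and str-206. The odds ratio was 0 to 0.195 in 12 alternatives, all past the threshold.

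The other 19 lists did not pass the threshold, and most are too short for 1 or 2 occupied genes to decide. Among housekeeping lists, constitutive chaperones had 2 of 15 occupied (hsp-1 and cct-8, odds ratio 9.69, exact adjusted p = 0.124), the spliceosome 2 of 30 (rsp-6 and snr-6, the latter by the peak at the 3′ end of pie-1, exact adjusted p = 0.294), the proteasome 1 of 33 (rpt-3, exact adjusted p = 0.850) and histones 1 of 72 (his-61, exact adjusted p = 1). The chaperones passed in 5 of 12 alternatives: a window of 1000 bp (odds ratio 10.3), without replicate 2 (16.95), any overlap with the window (14.2), a summit anywhere in the gene (18.5) and all pooled candidate regions (9.81); the proteasome passed with a summit anywhere in the gene (5.70) and with all pooled candidate regions (13.8). The summit at his-61 lay downstream of this short gene, 437 bp from its 5′ end. The proteasome genes pas-1 and pas-2 and the histone genes his-1 and his-12 were not occupied. No gene was occupied among the 23 of RNA polymerase II and general transcription, which include rpb-2, or among the 10 inducible heat shock genes, which include hsp-16.1 and hsp-16.2. In the male germline lists, 1 of 44 spermatogenesis genes was occupied (spe-48, exact adjusted p = 0.850; fer-1 and gsp-3 were not), as were 0 of 31 major sperm protein genes, such as msp-10 and msp-113. None of the tissue lists passed. The counts were 1 of 42 for muscle (act-4, with unc-54 and myo-1 unoccupied), 0 of 42 for neuron (unc-17 and cha-1 among them), 0 of 33 for intestine (elt-2 and elt-7 among them), 0 of 6 for vitellogenins (vit-1 and vit-2 among them) and 0 of 140 for neuropeptides (flp-1 and flp-10 among them). Of 172 cuticle collagen genes, 3 were occupied; col-85 and col-54 have the peak at a tRNA gene in an intron, and col-38 shares its peak with rpl-5.

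**Figure D4:**
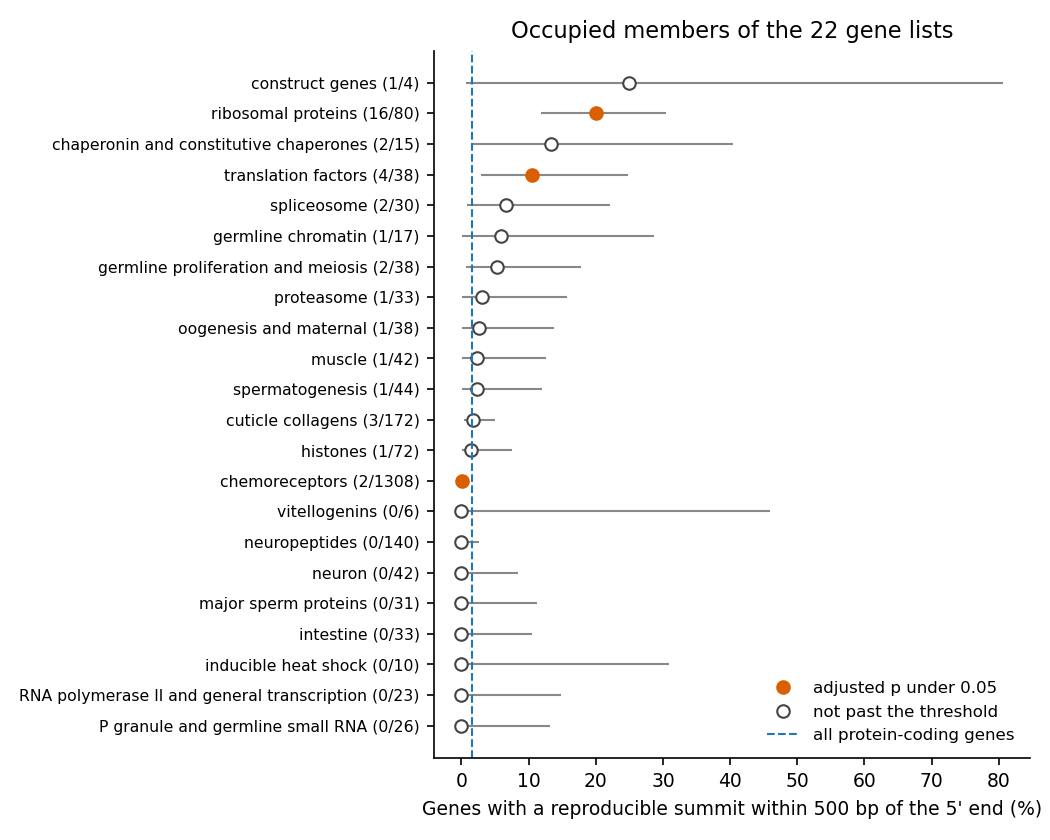
Percent of the members of each of the 22 gene lists that were occupied (points), with the 95% Clopper-Pearson interval (lines) and the occupied and total members in brackets. Filled points passed an adjusted p of 0.05 by Fisher's exact test, and the dashed line is the 1.57% of all protein-coding genes.

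The germline lists address the tissue in which the pie-1 promoter drives the tagged protein. Together they had 4 members occupied (3.36%, 0.923 to 8.38%), against 4 of 289 (1.38%) in the intestine, muscle, neuron and collagen lists. The difference was not detectable with these counts (odds ratio 2.47, 0.452 to 13.5, p = 0.239 by Fisher's exact test). Without the transgene genes, which include pie-1, 3 of 117 against 4 of 288 were occupied (odds ratio 1.87). The odds ratio was 1.22 without replicate 2, 4.97 with peaks away from small RNA genes, and 4.90 with a window of 250 bp and with the 443 strongest peaks. It passed the threshold only with all pooled candidate regions (2.66). The occupied germline genes were him-17 and brc-1, which act in meiosis and DNA repair (2 of 38 in that list, exact adjusted p = 0.376), pie-1 among the oogenesis genes (1 of 38, exact adjusted p = 0.850) and mrg-1 among the chromatin genes (1 of 17, exact adjusted p = 0.577). The mes-2, mes-3, mex-1 and mex-3 genes were not occupied, nor was any of 26 P granule and small RNA pathway genes. However, pgl-1, a core P granule component, had an optimal peak of rank 368 within 500 bp of the gene but away from its 5′ end.

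Of the 4 genes with sequence in the transgene, pie-1 had the most peaks. As a list they had 1 of 4 occupied (exact adjusted p = 0.270), and 2 of 4 with a summit anywhere in the gene, which passed the threshold (odds ratio 21.1). On chromosome III, 4 optimal peaks lay within 3000 bp of pie-1, which spans 12426893 to 12429195. Their summits were 2078 bp and 489 bp upstream of its 5′ end, in an intron 1091 bp downstream of it, and at the 3′ end of the gene, with ranks 845, 294, 497 and 804. Among the 887 strongest regions, replicate 1 had 2 and replicate 2 had 4 at this locus. Of all nuclear protein-coding genes, 7 had at least 4 peaks within 3000 bp, among them 2 of up to 5 kb, pie-1 and Y65A5A.1; within 500 bp of the gene, pie-1 was 1 of 15 genes with at least 3 peaks, 7 of them of up to 5 kb. These comparisons were chosen after the data had been seen. Reads from the pie-1 promoter of the transgene cannot be told apart from those of the endogenous gene. At unc-119, a single optimal peak (rank 779) lay 2762 bp downstream of the 5′ end. No optimal peak was near puf-5, whose best pooled region had rank 1352, and no region of any list lay within 3000 bp of ama-1 itself.

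**Figure D5:**
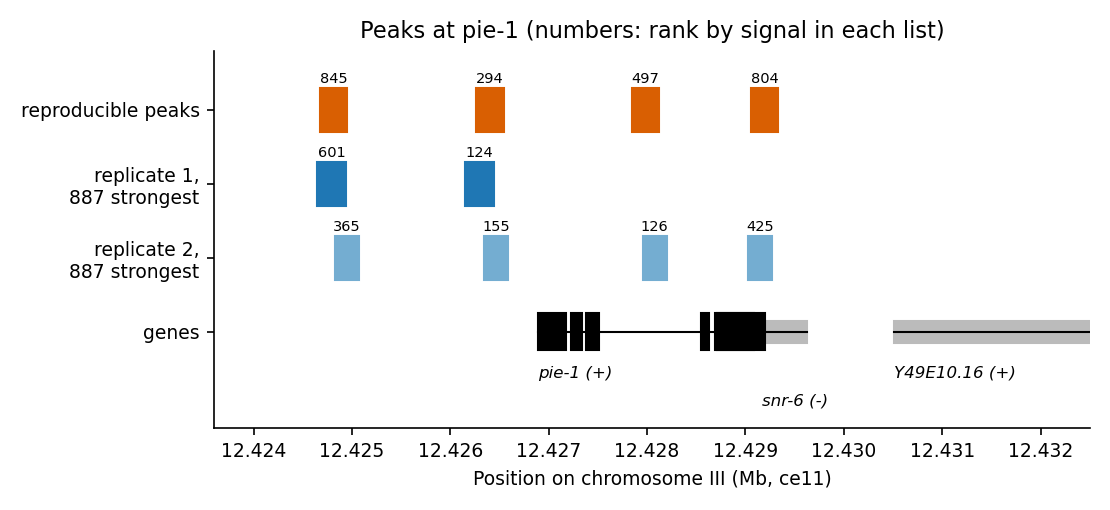
Peaks at pie-1 on chromosome III (ce11, position in Mb) in the optimal list and among the 887 strongest regions of each replicate, with the rank of each region by signal above it; black boxes are pie-1 exons and grey boxes neighbouring genes. Optimal peaks span 2078 bp upstream of the 5′ end to the 3′ end of the gene.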

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

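The test in this part was chosen after the result had been seen. The 29 reproducible peaks on the mitochondrial genome stood out as signal in data that the comparisons of nuclear genes do not use; they are summits within 2 called intervals and not 29 separate regions. Unequal mitochondrial DNA content of the ChIP and control libraries is a candidate explanation: candidate regions covered at least 97.1% of the mitochondrial genome in each replicate, in 2 intervals with 25 summits in replicate 1 and 3 intervals with 33 summits in replicate 2. Coverage alone met what this explanation predicts, although a few long intervals fix most of it. The further condition that the signal be even was added once the signal was known to span 76.4-fold across the 29 peaks, from 61.7 to 4717, and it was not met. Since the reads of ChIP and control were not analysed here and the scale of the signal is not given, the values leave it open. No biological explanation was tested, because the design has a single group.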

How the results depend on the processing

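The alternatives with peaks away from small RNA genes, with all pooled candidate regions, with nuclear chromosomes only and without the transgene genes, and those for tRNA results and all candidates in each replicate, were chosen after the data had been seen. Of 94 alternatives for the main comparisons, 78 kept the direction and the side of the threshold or, for counts, stayed near the main count. Among them were all those for replicate overlap (26.3 to 38.1%), for peaks near 5′ ends (1.30 to 2.13 times the comparison set) and 3′ ends (1.63 to 3.004). The number of gene classes past the threshold stayed at 5 to 8, but that count hides changes in single classes. The stronger part of the list has 443 peaks by construction. With it the X odds ratio was 0.788, not past the threshold, and that for chromosome centres was 0.842, reversed, with no call either way. A window of 1000 bp gave 0.808 for X, no longer past the threshold, and 1.24 for centres, now past it, and turned the difference in median rank of 5′ peaks to 0.564 percentile points, uncalled. With a summit anywhere in the gene, centres passed (1.19), the operon-like difference did not (1.17), and 6 gene lists passed. A window of 250 bp left 1 list. All pooled candidate regions gave 14 lists, and calls for centres (1.28) and for germline against soma (2.66). Without replicate 1 or without replicate 2, the odds ratio was 0.533 to 0.678 for X, 1.13 to 1.37 for centres, and the difference in median rank was -3.95 to 0.620 percentile points. For single classes, protein-coding genes reversed with a summit anywhere in the gene (1.57), with all candidates (1.53) and away from small RNA genes (3.13), where tRNA and snRNA genes fell to 0, since most of their summits lie within the 250 bp that this alternative leaves out. Translation factors had an odds ratio of 0 in the stronger part of the list; 135 of 168 alternatives for single classes, lists and tRNA results kept direction and call. With all candidates, neuropeptides were at 0.732 without replicate 1 and at 1.01, reversed, without replicate 2. The causes of the other changes were not tested. No paired analysis was possible because there was a single group. With depth unknown, an unoccupied gene may lie just under the threshold, but how many do is not known. Some pooled candidate region lay at the 5′ end of 5795 protein-coding genes (29.0%), and using these made the germline odds ratio 2.66. By its name, that list includes background regions. At ranks 20001 to 30000, 18.6% of its regions lay at protein-coding 5′ ends away from small RNA genes. The shifted mean for the optimal peaks was close to that, at 17.5%.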

Other observations

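The tests of candidate regions below the threshold, of the lists in all candidate regions, of shared tRNA stretches and of tRNA copy number in this part were chosen after the results had been seen. When any of the 30000 pooled candidate regions counted, 6 lists of genes for translation, protein turnover and folding, splicing and transcription were occupied more often than other protein-coding genes. A region lay at the 5′ end of 73 of 80 ribosomal protein genes (odds ratio 25.8, adjusted p = 1.38e-30 by Fisher's exact test), 28 of 33 proteasome genes (13.8, adjusted p = 2.86e-10), 12 of 15 constitutive chaperone genes (9.81, adjusted p = 0.000207), 23 of 30 spliceosome genes (8.07, adjusted p = 4.85e-07), 25 of 38 translation factor genes (4.72, adjusted p = 2.19e-05) and 16 of 23 genes of RNA polymerase II and general transcription (5.61, adjusted p = 0.000207). These 6 lists passed with the candidate regions of either replicate, but without replicate 2 the odds ratios were 9.78, 3.14, 5.23, 2.62, 4.02 and 3.403 in that order. P granule genes (15 of 26, odds ratio 3.34, exact adjusted p = 0.00805), germline chromatin genes (11 of 17, 4.50, adjusted p = 0.00583) and neuronal genes (21 of 42, 2.45, adjusted p = 0.0102) were also above the rest in the pooled list. Of these, P granule genes passed in neither replicate alone (odds ratios 2.24 and 2.202), germline chromatin genes not without replicate 2 (2.94), and neuronal genes not without replicate 1 (1.0998). Major sperm protein genes (2 of 31, odds ratio 0.169, exact adjusted p = 0.00897), histone genes (12 of 72, 0.489, adjusted p = 0.0324), neuropeptide genes (29 of 140, 0.638, adjusted p = 0.0492), collagen genes (31 of 172, 0.536, adjusted p = 0.00347) and chemoreceptor genes (45 of 1308, 0.0801, adjusted p = 1.34e-133) were below it. Major sperm protein genes (0 of 31 in each replicate) and chemoreceptor genes (0.178 without replicate 2 and 0.130 without replicate 1) passed in both replicates, whereas neuropeptide genes (1.01 and 0.732) and collagen genes (0.870 and 0.686) passed in neither, and histone genes not without replicate 2 (0.630).

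A germline preference among the weaker regions was tested as a hypothesis. Leaving out regions that overlap an optimal peak, germline genes exceeded somatic genes in the pooled list (46.2% against 24.6%, odds ratio 2.63, p = 3.17e-05 by Fisher's exact test) and in replicate 2 (odds ratio 2.202, p = 0.000517). In replicate 1 the odds ratio was 1.27 (0.788 to 2.04, p = 0.297 by Fisher's exact test), so the requirement that both replicates pass was not met. The preference may rest on replicate 2, and whether the replicates differ was not tested. Of the 289 somatic genes, 172 are cuticle collagen genes. With all pooled candidate regions, 31 of those 172 and 6 of 33 intestine genes were occupied. Muscle genes had 16 of 42 and neuronal genes 21 of 42. The germline lists ran from 14 of 38 (proliferation and meiosis) to 11 of 17 (chromatin). The pooled excess was thus not over every somatic list, and how much of it rests on collagen genes was not tested.

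Occupancy of tRNA genes far above that of protein-coding genes does not need neighbouring protein-coding genes: of 304 nuclear tRNA genes with no protein-coding end within 1000 bp, 48.0% were occupied (42.3 to 53.8%). Genes whose sequence occurs once were occupied in 37.9% of cases (29.8 to 46.4%). That share cannot exclude shared reads, since such a gene can still share stretches with near-identical copies. Of the 25 in which every 36 bp stretch is unique in the genome, 3 were occupied (12%, 2.55 to 31.2%). This was above the 1.57% of protein-coding genes (odds ratio 8.54, 1.63 to 28.6, p = 0.0070 by Fisher's exact test). The difference rests on 3 genes, and the 500 bp window also takes in summits at neighbouring genes. Only exact 36 bp matches were counted as shared, so copies with mismatches could still share reads, and the aligner is not given. These genes therefore cannot decide whether shared reads are the whole source. How much shared reads add stays open: those 25 were occupied less often than the other 587 tRNA genes (odds ratio 0.131, p = 0.000119 by Fisher's exact test), and genes with 10 or more copies more often than those with 1 copy (odds ratio 2.15, p = 0.000249), which shared reads could give, as could lower transcription of unique genes, which was not tested. Recovery of open chromatin irrespective of AMA-1 is a further candidate explanation that was not tested, since no control precipitation was analysed here. No biological explanation was tested.

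Ribosomal protein genes kept their odds ratio, 18.5 (8.88 to 35.5, p = 2.85e-11 by Fisher's exact test), without the 13 members that have a tRNA, snoRNA or snRNA gene within 500 bp of the 5′ end, with 12 of 67 occupied. Their 16 occupied members lay at percentile 100 of 10000 random lists matched on gene length, which had a mean of 1.12 and at most 7 occupied members. Both tests argue against small RNA genes beside them and against short genes as the whole source of the difference. High transcription is a candidate explanation that was not tested, since no expression data were analysed here.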
